A study of Mus musculus with 6 samples.

How the data were processed

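TERT, the catalytic protein subunit of telomerase, was mapped on chromatin by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA beside the bound protein. The cells were primary neurons from the cortex and hippocampus of embryonic C57BL/6 mice. Per the labels' protocols, 3 samples received vehicle (dimethyl sulfoxide) and 3 received 2 µM BIBR1532, a small-molecule telomerase inhibitor, for 24 h. One label field calls the vehicle samples untreated, and the treatment protocol was followed here. Samples were grouped by the dose in their titles.

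The submitters' processing notes name CASAVA 1.8, Bowtie2, Picard and MACS2 2.1.2, and the mm10 genome build, with no role or order for each. The names of the deposited lists show that the 3 libraries of each condition were combined and compared. They do not name the program: the bdgdiff step of MACS2, with a threshold of 1, was inferred from their form. That step sorted regions into 3 lists: higher in the first condition, higher in the second, and common to both. Per the file headers, the regions were annotated on mm10 with annotatePeaks.pl, which assigns each region a class and the gene with the nearest transcription start site. The deposited score of each region is the authors' own value, and how the pools were scaled is not given in the sources used here. In MACS2 this score is a log10 likelihood ratio, which is known from the program and not stated with the data. It was used to rank, filter and describe regions within a list. Steps added after seeing the data also set the lists side by side at a shared score limit of 3 and fitted the repeated scores of both lists to whole pileups, from which a depth ratio of the pools was taken.

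The first condition was taken as BIBR1532 and the second as vehicle from the order in which they stand in the names of the lists. This is the convention of bdgdiff, so the direction of each comparison is likely and not stated outright. The BIBR1532 list holds regions with higher signal in the BIBR1532 pool, the vehicle list those with higher signal in the vehicle pool, and both are called condition-specific below. Both had been saved in a 7-bit text encoding and were decoded before use.

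Each condition is 1 pooled measurement. The depth of each sample is unknown from the lists, and no test across replicates, no test with a library left out and no count of sample splits could be made. Fisher's exact test (two-sided) on regions therefore compares the deposited lists, not the conditions. Exact (Clopper-Pearson) binomial intervals at 95% cover counting error only. Intervals of odds ratios are normal-approximation (Wald) intervals at 95%, not exact ones, and also cover counting error only. Regions on chromosomes 1 to 19, X and Y were used, and annotation classes, repeat classes and chromosomes were each adjusted by Benjamini-Hochberg.

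Proximity of the BIBR1532 list to the vehicle list was set against 100 circular shifts of the vehicle regions along each chromosome, for which the smallest two-sided p is 0.0198. For 31 gene lists, the BIBR1532 share of the condition-specific regions was ranked among 10000 random lists, drawn with replacement from genes with like numbers of regions. Of 920 distinct genes in those lists, 758 were named by at least 1 region and 920 matched the RefSeq table of the same build, which gave gene positions and lengths. Of 15356 genes named by any region, 15345 (99.9%) matched that table by gene ID.

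The groups, tests, gene lists and most alternatives were fixed before the data were examined. The genes and regions named follow a rule fixed with them. It takes the 5 regions of highest score in each list and the 5 promoter regions of highest score in each condition-specific list. It also takes the 5 genes with the largest excess each way, up to 4 members of each described list with the most condition-specific regions, and Tert, Terc, Ctnnb1, Myc, Ccnd1, App, Mapt and Bdnf whatever their values. Some items that this rule takes are not reported here. Members named for their common promoter regions, or for a promoter region in a single list, were chosen after their values were seen.

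Several steps were chosen after seeing the data: the setting without the regions at the most frequent score of their list, the counts by score range, the share of list members with a common promoter region, the regions per gene length, the binomial tests on genes and on list promoters, and the gene overlap over protein-coding genes. The alternatives fixed beforehand were score minimums of 2 and 3, a width of at least 500 bp, merging of regions within 1 kb, all contigs, promoter windows of 1 and 5 kb, base pairs in place of regions, neighbour distances of 200 bp and 5 kb, and assignment of regions within 10 kb only. For the gene lists, they were leaving out the member with the most regions, random lists without matching, and genes in place of regions.

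Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The steps were tested on simulated data. A promoter share raised 1.5 times was called in 100% of 100 simulated list pairs, and any of 8 classes was called in 6% of 100 pairs with no change. Over 13643 genes, simulated gene lists with no change fell outside the central range in 1.28% of 78 cases, and those with a BIBR1532 share of 0.65 in 100% of 15. The simulated lists held only genes with more than a single condition-specific region, so these rates do not carry over to lists with few regions. For microglial markers, with 19 regions, the central range reached 70.6%, and a share of 0.65 would lie inside it. With 1000 simulated positions the permutation by circular shift gave p = 0.337 for independent positions and p = 0.0198, the smallest it can give, when neighbours had been placed together. Sequence content was not analysed here because no genome sequence was used.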

Results

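The data were 3 lists of TERT CUT&Tag regions from mouse primary neurons, each made from the combined libraries of 3 vehicle-treated and 3 BIBR1532-treated samples. On chromosomes 1 to 19, X and Y, the common list held 6812 regions, the BIBR1532 list 16153 and the vehicle list 18562. Covered lengths were 2153 kb, 6616 kb and 7456 kb, and median widths were 257, 247 and 244 bp. There are no replicate values behind any region, and the depth of the samples is unknown from the lists.

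The first question was where TERT signal lay when it was shared by both conditions. Common regions lay at promoters. Of them, 51.9% were annotated as promoter-TSS, the class around a transcription start site, against 10.2% of the 34715 condition-specific regions (Fisher's exact test on the lists, odds ratio 9.53, 95% interval 8.99 to 10.1). Without the regions at the most frequent score of their list, promoters were 17.3% of the BIBR1532 and 17.3% of the vehicle regions, so the contrast was smaller. Regions in a 5' UTR were also more frequent among common regions, at 5.48% against 1.18%, whereas introns took 18.3% against 43.9% and intergenic sequence 13.5% against 38.6%. The region centre lay within 1 kb of a transcription start site in 72.7% of common regions, 17.6% of BIBR1532 regions and 15.9% of vehicle regions. In all, 7 of the 8 classes differed between common and condition-specific regions after adjustment. The exception was the class around transcription termination sites (1.81% against 1.53%, Fisher's exact test, adjusted p = 0.0993).

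**Figure D1:**
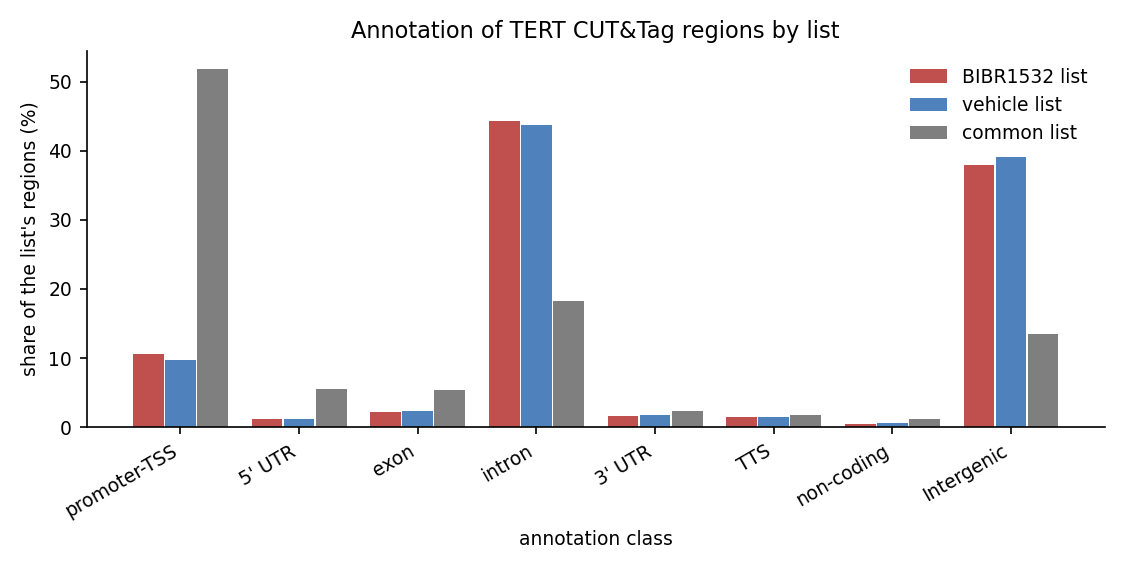
Share of each list's regions (y axis, percent) in 8 annotation classes (x axis) for the BIBR1532, vehicle and common lists. Common regions are mostly promoter-TSS (51.9%), whereas introns and intergenic sequence hold most regions of both condition-specific lists.

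Heat shock, chromatin and proteasome genes had a common promoter region more often than random lists of genes did. Of 21887 protein-coding genes, 3109 (14.2%) had a common promoter region. The random lists were not matched on expression, and no control library is among the samples. The shares below therefore describe the lists and do not tie TERT to any gene function. In the list of heat shock and unfolded protein response genes 14 of 27 had one, among them the chaperone genes Hspa8, Hspa4, Hspa5 and Hsp90b1. Of 38 chromatin regulators 17 had one, including the polycomb genes Ezh2 and Eed and the acetyltransferase gene Ep300. The share was also above the central 95% of random lists for proteasome subunits (11 of 31, such as Psmb1 and Psmc4), antioxidant genes (9 of 28, such as Sod2 and Prdx1), ribosomal proteins (12 of 39, such as Rplp0 and Rps14), immediate early genes (8 of 26, such as Fos, Jun and Egr1) and DNA repair genes (10 of 33, such as Ogg1 and Xrcc5).

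Synaptic lists were not set apart by their common promoters. Presynaptic release genes had 7 of 35, above the share over all genes, and postsynaptic scaffold genes 3 of 30, both inside the central range. Of 32 glutamate receptor genes, 1 (Grin3a) had a common promoter region, at percentile 2.80 of the random lists, just inside the central range. Cell adhesion genes had 3 of 46 and voltage-gated ion channels 3 of 40, both also inside it. Among markers of other cell types, endothelial and mural markers had 0 of 22, at the lower edge of the range, which is itself 0 (percentile 1.66, with ties counted in part). Microglial markers had 0 of 18 (percentile 3.07), oligodendrocyte lineage markers 1 of 18, neural progenitor markers 1 of 18 and astrocyte markers 3 of 18, all inside the range. Of the 22 telomere and shelterin genes, Dkc1, Nhp2, Pinx1 and Ten1 had a common promoter region, also inside the range. In all, 7 of 31 lists lay above the range, and 8 were outside by percentile with endothelial and mural markers at its edge, where chance gives about 1.55. DNA repair was lost from them when random lists were matched on gene length, and with common regions of at least 500 bp 2 lists lay outside, chromatin regulators (5 of 38) and cell cycle (4 of 34). With region centres within 1 kb of a start site in place of the promoter class, 15 lists lay outside. Glutamate receptors (percentile 0.565), voltage-gated ion channels (2.42) and microglial markers (0.995) then fell below the range, and endothelial and mural markers were lowest (0.485). In that setting neuronal cytoskeleton (percentile 99.9), Alzheimer-associated genes (99.6), RNA polymerase I and nucleolus (99.0) and autophagy and lysosome genes (98.5) lay above it.

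**Figure D2:**
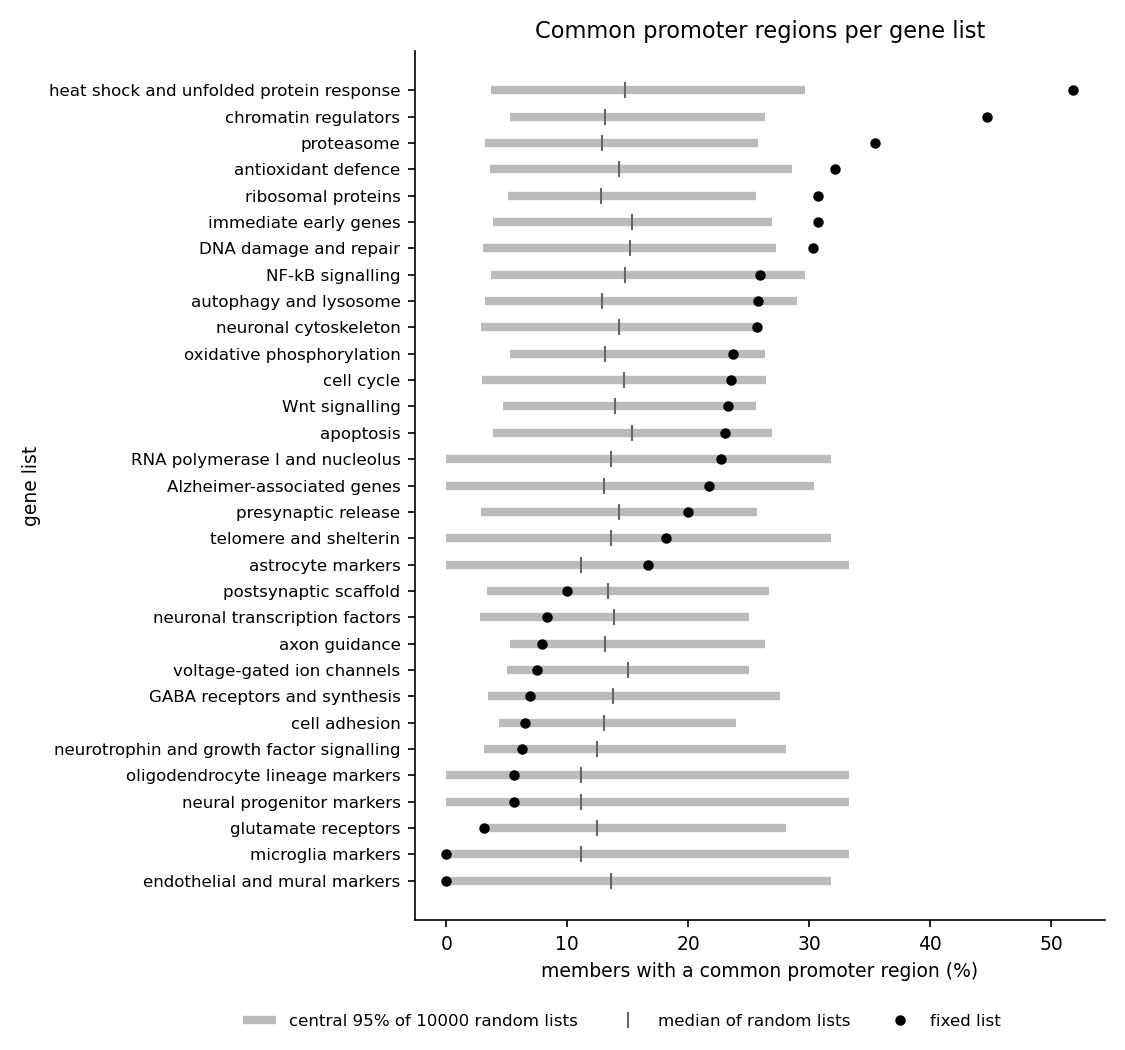
Percent of each gene list's members with a common promoter region (x axis) for 31 gene lists (y axis). Points are the lists, grey bars the central 95% and ticks the median of 10000 random lists. Heat shock and unfolded protein response genes lie highest, at 51.9%.

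The second question was how the regions differed between vehicle and the inhibitor. Regions were called in both directions in like numbers: BIBR1532 regions made up 46.5% of the condition-specific regions (exact interval 46.0 to 47.1) and 47.0% of their covered length. Introns held 44.3% of the BIBR1532 and 43.7% of the vehicle regions, and intergenic sequence 37.9% and 39.1%. Among regions with an authors' score under 3, a limit shared by both lists and added after seeing the data, 2497 were BIBR1532 and 1781 vehicle regions, a BIBR1532 share of 58.4%. At a score of at least 3 the share was 44.9%. Equal pileups score differently in the lists, and a computed pileup of 4 against 1 was a score level of 494 BIBR1532 regions and not of the vehicle list, so a shared limit takes different pileups in each list.

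A large part of both lists sat at 1 score. In the BIBR1532 list 7563 regions (46.8%) had the authors' score of 6.34, and in the vehicle list 9312 (50.2%) had a score of 5.19. These tied regions were rarely promoters, at 2.94% and 2.29%, whereas the regions of lower score were promoters in 28.5% of the BIBR1532 and 40.9% of the vehicle list. Regions above the tied score were promoters in 7.94% and 9.07%. Every gene and list count of condition-specific regions below includes them unless stated.

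**Figure D3:**
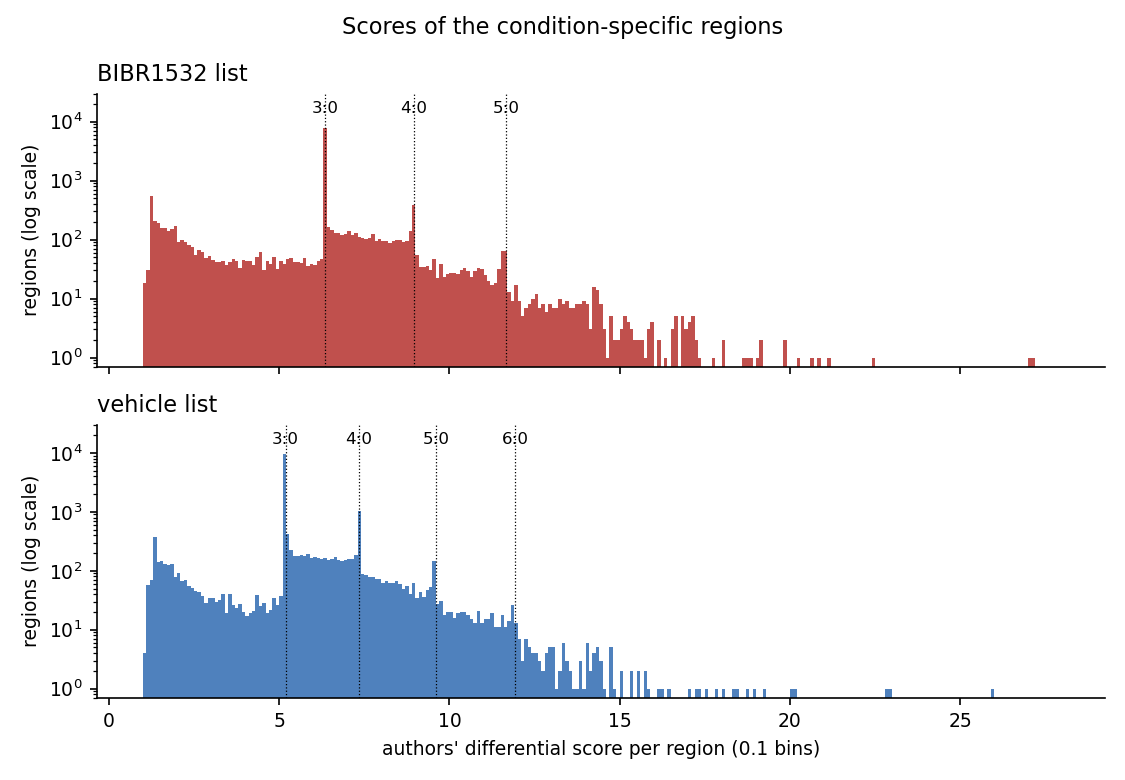
Number of regions (y axis, log scale) by the authors' score (x axis, bins of 0.1) in the BIBR1532 and vehicle lists. Dotted lines mark the scores computed for whole pileups in the list's own pool against 0 in the other, and the highest bars, at 6.34 and 5.19, hold 46.8% and 50.2% of the regions.

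Taken over all scores, promoter regions made up slightly more of the BIBR1532 list than of the vehicle list. They were 1711 regions (10.6%) against 1814 (9.77%), an odds ratio of 1.09 (95% interval 1.02 to 1.17, Fisher's exact test p = 0.0120). Over the 8 classes the adjusted p was 0.0861 for promoters and also for intergenic regions, so 0 of the 8 passed. Among regions of at least 500 bp 2 classes passed, introns (43.9% of BIBR1532 against 40.3% of vehicle regions, adjusted exact p = 0.0316) and intergenic regions (47.8% against 51.9%, adjusted exact p = 0.0195). Without the tied regions the promoter shares were 17.3% and 17.3% (odds ratio 1.002, Fisher's exact p = 0.968). Below each list's tied score the shares were 28.5% against 40.9% and above it 7.94% against 9.07%, the opposite direction. At the tied score they were 2.94% against 2.29%. The promoter-rich range below the tied score held 24.3% of the BIBR1532 and 12.9% of the vehicle regions. A computed pileup of 4 against 1 was a score level of the BIBR1532 list and not of the vehicle list. This range therefore takes different pileups in each list. How far that accounts for the promoter shares and odds ratios given here was not tested. Among regions of at least 500 bp the promoter odds ratio was 1.02 (exact p = 0.889) and at a score of at least 3 it was 1.08 (p = 0.0912). For regions within 5 kb of a transcription start site it was 1.18 (exact p = 6.3e-11), and 1.08 (p = 0.0147) without the tied regions.

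The promoters of highest score in the BIBR1532 list included those of the antiproliferative gene Btg2 (score 17.3), Tmem88 (17.3), the diacylglycerol kinase gene Dgkb (17.1) and Nhsl1 (15.5). The Btg2 region spanned 134079431 to 134079828 on chromosome 1 of mm10. In the vehicle list they were those of Nle1 (23.0), the vesicle coat gene Sec24c (15.7), Atxn2l (14.8), the neuroendocrine transcription factor gene Insm1 (14.6) and the Rab GTPase gene Rab36 (13.9). The Nle1 region spanned 82908351 to 82908751 on chromosome 11. Btg2 also had a common promoter region.

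Over all classes, the BIBR1532 regions of highest score were nearest to Mir29b-1 (27.2), Lbx2 (27.1, exon 1 of 2), 1700125H03Rik (22.5), Atxn1 (21.1, intron 2 of 6) and Crim1 (20.8, intergenic). In the vehicle list they were nearest to Ift81 (25.9), Nle1, Mir100hg (22.9), Myc (20.2) and 1700061F12Rik (20.1). The common regions of highest score, all at promoters, belonged to Nkiras1 (0.913), Btf3l4 (0.899), Wdr37 (0.875), Ddx54 (0.875) and Pkmyt1 (0.873). In this list a higher score marks a larger difference between the pools. A computed pileup of 3 in both pools scored 0.0124, so this ranking does not give the strongest shared sites.

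Few regions lay near the telomerase genes themselves. Tert had 1 BIBR1532 region, at 73628142 to 73628436 on chromosome 13 in exon 2 of 16, at the tied score, and no vehicle or common region. Terc, the telomerase RNA gene, had 1 intergenic region in each condition-specific list, both more than 10 kb from its start site. Of the Wnt pathway genes fixed by name, Myc had 1 vehicle region, at 61986994 to 61987341 on chromosome 15 in intron 1 of 2, and Ccnd1 and the β-catenin gene Ctnnb1 had 0 in every list. Mapt, which encodes tau, had 4 BIBR1532, 1 vehicle and 1 common region. Its BIBR1532 region at 104230815 to 104230935 on chromosome 11 was at a promoter. That region was 121 bp wide and scored 2.00, the level computed for a pileup of 5 against 1. The common region lay 182 bp and the vehicle region 1051 bp from the same start site, so this promoter also held shared signal. App, the amyloid precursor gene, had 2, 3 and 1. Bdnf, which encodes a neurotrophin, had 1 BIBR1532 region, at a promoter at 109722392 to 109723031 on chromosome 2. With 1 pooled measurement per condition, these single regions have no replicate check.

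Repeats and chromosomes did not separate the lists. Repeat-annotated regions made up 25.2% of the BIBR1532 and 25.5% of the vehicle list, against 4.42% of the common list. Telomeric repeats were named in 2 BIBR1532, 1 vehicle and 2 common regions. This counts regions whose annotation on mm10 names the repeat, and it does not measure TERT signal at chromosome ends. LTR elements (5.91% against 6.35%, exact p = 0.0973, adjusted p = 0.956) had the smallest p among repeats, and 0 of 10 repeat classes and 0 of 21 chromosomes passed after adjustment. Chromosome 1 had the smallest p among chromosomes (7.21% against 6.63%, exact p = 0.0338, adjusted p = 0.411).

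BIBR1532 and vehicle regions lay close together more often than shifted positions did. Of the BIBR1532 regions, 814 (5.04%) lay within 1 kb of a vehicle region, against 1.98% after circular shifts, a ratio of 2.54 (permutation by circular shift, p = 0.0198, the smallest that 100 shifts can give). Within 200 bp the ratio was 0.958 (permutation by shift, p = 0.535), and among regions of at least 500 bp it was 1.14 (p = 0.713). Without the tied regions it was 5.74.

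At the level of genes, the lists shared part of the genes they named. The BIBR1532 list named 9107 genes and the vehicle list 9868, with 5332 shared (58.5% of the BIBR1532 genes). The share was 25.7% for regions of at least 500 bp, 26.4% within 10 kb of a start site and 42.3% without the tied regions. Independent lists over the 15356 genes named by any list would share 5852, a value that is high by construction because genes named by no list are left out. Over all 21887 protein-coding genes, 4388 were shared where independent lists would share 2827. That value is low by construction, because it takes every gene as equally likely to be named. Condition-specific regions per gene rose with gene length (Spearman rho 0.279 across genes), so unrelated lists would also share more than 2827.

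The largest differences in region number lay at protein-coding genes, most of them long, and at 3 non-coding genes or pseudogenes. In the BIBR1532 direction these were the sialyltransferase gene St6galnac3 (11 BIBR1532 and 2 vehicle regions), Anks1b (16 and 8), the transcription factor gene Tox3 (17 and 9) and the non-coding genes 1700012D16Rik (10 and 2) and 4930474N09Rik (9 and 2). The gene 1700012D16Rik lies inside St6galnac3, so these entries share a locus that was divided by nearest start site. The binomial test below took them as separate genes. In the vehicle direction the largest differences included Frmd4a (3 and 15), the cell adhesion gene Lsamp (14 and 24), Setbp1 (0 and 10) and the pseudogene Zp4-ps (3 and 13). By an exact binomial test, 0 of 13643 genes passed after adjustment and 112 had an unadjusted p under 0.05. Without the tied regions the excess of Tox3 was -2, among regions of at least 500 bp that of Anks1b was -1, and within 10 kb of the start site Lsamp had an excess of 2 in the BIBR1532 direction.

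Of the 31 gene lists, apoptosis alone lay outside the central 95% of random lists. It had 23 BIBR1532 regions of 36 (63.9%, percentile 97.8), with the pro-apoptotic gene Bcl2l11 at 6 and 1, Bbc3 and Fadd each at 3 and 1, and Apaf1 at 2 and 2. The list was back inside the range without Bcl2l11, at a score of at least 2 or 3, within 10 kb of the start site, with genes as units, and without the tied regions. Its share was 65% without the tied regions and 57.1% to 61.5% in the other settings named. At a score of at least 3 and without the tied regions, the 1 list outside the range was therefore another. Chance gives about 1.55 such lists of 31.

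Synaptic lists were near balance. Glutamate receptor genes had 69 BIBR1532 regions of 127 (54.3%, percentile 95.2), with Gria1 at 8 and 7 and Grm7 at 4 and 7. Postsynaptic scaffold genes had 79 of 177 (44.6%), with Dlg2 at 15 and 16 and Dlgap1 at 10 and 10. Presynaptic release genes had 70 of 146 (47.9%), with Nrxn3 at 9 and 18 and Ppfia2 at 8 and 3. GABA receptor and synthesis genes had 30 of 74 (40.5%), with Gabrg3 at 2 and 7. Voltage-gated ion channels had 71 of 152 (46.7%), with Cacna1e at 8 and 2.

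Lists for neuronal shape and identity were also inside the range. Axon guidance genes had 101 of 246 (41.1%, percentile 4), with Efnb2 at 6 and 13 and Robo1 at 10 and 10. Cell adhesion genes had 206 of 454 (45.4%), with Ntm at 16 and 13 and Pcdh9 at 8 and 14. Neuronal cytoskeleton genes had 61 of 112 (54.5%, percentile 95.2), with Dclk1 at 7 and 3. The neuronal transcription factor list had 90 of 190 (47.4%), with Nfia at 3 and 10. It also holds genes of RNA-binding proteins, such as Rbfox1 at 13 and 15. Immediate early genes had 34 of 71 (47.9%), with Klf4 at 3 and 9, and neurotrophin and growth factor genes 65 of 121 (53.7%), with Ntrk2 at 5 and 5.

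Signalling, stress and disease lists did not stand apart either. Wnt signalling genes had 67 of 131 (51.1%), with Wnt5a at 7 and 5 and Fzd8 at 2 and 7. NF-kB genes had 11 of 29 (37.9%), telomere and shelterin genes 11 of 26 (42.3%, with Terf1 at 1 and 5) and Alzheimer-associated genes 28 of 52 (53.8%). Heat shock and unfolded protein response genes had 20 of 40 (50%), with Hspa8 at 1 and 6. Antioxidant genes had 26 of 54 (48.1%), autophagy and lysosome genes 19 of 44 (43.2%) and proteasome genes 19 of 37 (51.4%).

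The remaining lists of cellular functions were inside the range as well. Oxidative phosphorylation genes had 8 of 26 (30.8%, percentile 4.25), ribosomal proteins 14 of 38 (36.8%) and RNA polymerase I and nucleolus genes 6 of 14 (42.9%). DNA repair genes had 18 of 34 (52.9%), with Lig4 at 4 and 0. Cell cycle genes had 32 of 57 (56.1%), with Mcm5 at 6 and 0, and chromatin regulators 58 of 118 (49.2%), with Hdac9 at 9 and 6.

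Markers of other cell types were inside the range in every case. Astrocyte markers had 21 of 45 (46.7%), oligodendrocyte lineage markers 10 of 28 (35.7%, with Olig2 at 0 and 5), microglial markers 12 of 19 (63.2%, with Sall1 at 7 and 2), endothelial and mural markers 5 of 18 (27.8%) and neural progenitor markers 26 of 48 (54.2%, with Notch2 at 5 and 0).

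**Figure D4:**
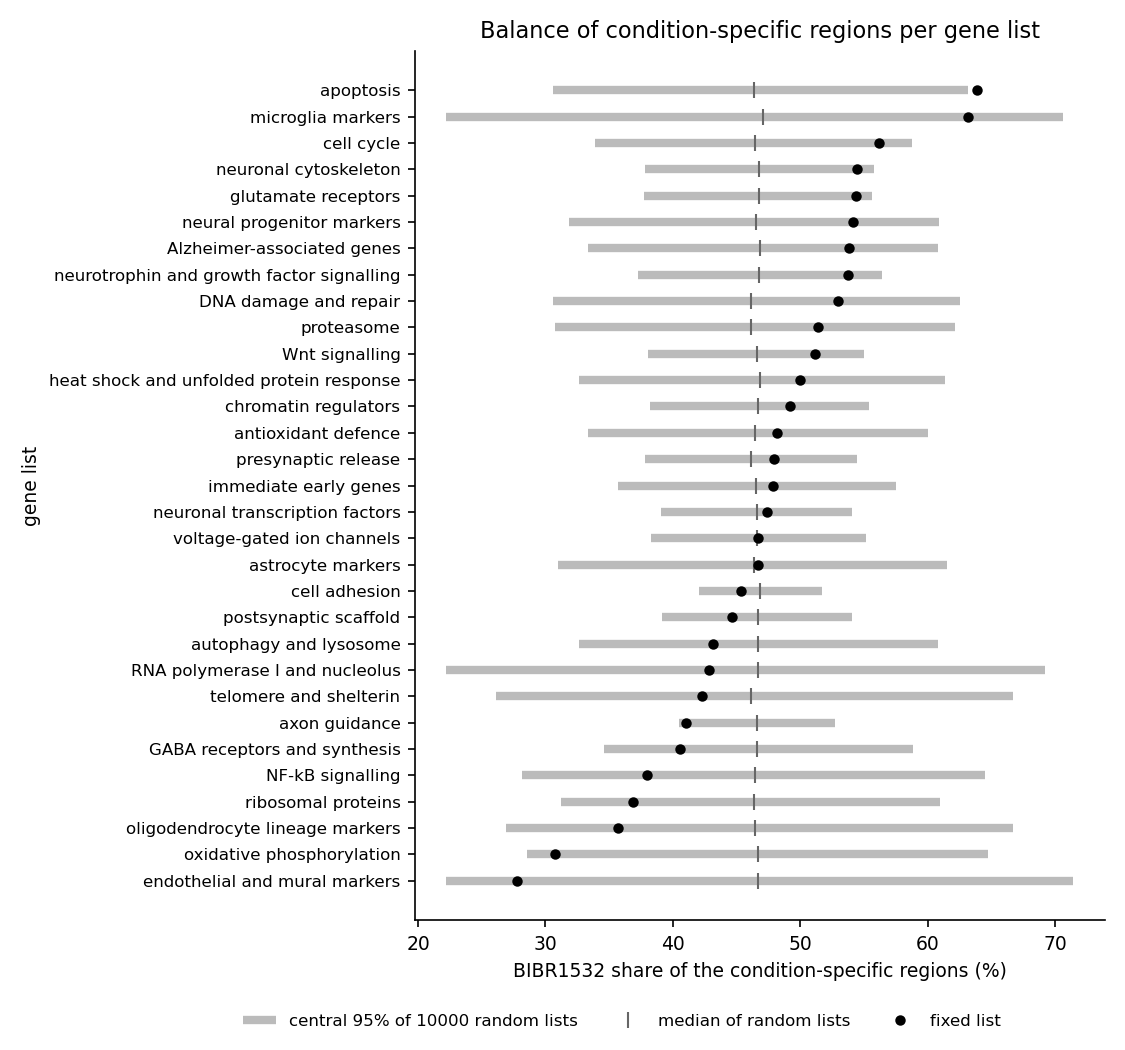
BIBR1532 share of the condition-specific regions (x axis, percent) for 31 gene lists (y axis). Points are the lists, grey bars the central 95% and ticks the median of 10000 random lists with like numbers of regions per gene. Apoptosis, at 63.9%, is the one point outside its bar.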

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

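Of the tests below, the pileup, binding and depth tests were chosen only after the values they use were seen. The test on regions inside the gene was added after the first gene length test had given its result, although its own value had not been seen.

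The mitochondrial chromosome, which the comparisons leave out, carried 2 BIBR1532 regions and no vehicle or common region. They spanned 230 to 6648 (score 18.3) and 10890 to 16131 (score 19.6).

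The most frequent score of each list, held by 16875 regions (48.6% of the condition-specific regions), matched a computed value for very few reads. With the MACS2 likelihood-ratio formula and a pseudocount of 0.01, both known from the program, 6 repeated scores fitted whole pileups of 3, 4 and 5 against 0 with a largest residual of 2.98e-06, where the next best start gave 0.596. For scattered background, the bound set before the test was a share near common regions at most 2 times that of shifted positions: the BIBR1532 tied regions were at 1.85 times, within the bound but above all 100 shifts, and the vehicle ones at 0.804 times. Background reads may therefore account for many tied regions. Shifted positions take background as unrelated to the common sites. The excess of BIBR1532 tied regions near those sites therefore cannot tell uneven background from binding. Binding that depends on BIBR1532 stays open, since a pileup of 3 against 0 has an exact binomial p of 0.1005 in the BIBR1532 list and 0.254 in the vehicle list, and pooled lists hold no replicates.

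The vehicle list held 1.15 times as many regions as the BIBR1532 list, and the fitted scores give a vehicle pool 1.15 times as deep. That match was first taken as the test, but its bound had been set with both values known, so it was replaced. At equal binding, regions of 3 against 0 should follow the depth ratio to the power 3, 1.53, and they stood at 1.23, which is 0.807 of it. The test is undecided because regions of 4 against 0 stood at 3.74 where 1.76 is computed. Regions were counted only where the score matched the computed level, 211 in the BIBR1532 and 789 in the vehicle list. Above the tied score the lists held 4671 and 6857 regions, so most higher regions were not in this count. The power may not hold for so small a part, and whether the calling treated equal pileups alike was not tested. Depth and an effect of the inhibitor cannot be told apart here.

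Long neuronal genes carried the most condition-specific regions, and gene length is a candidate explanation. Per 100 kb of gene, the cell adhesion list lay at percentile 98.8 of length-matched random lists, outside the range that length alone allows. That count includes regions between genes, and with regions inside the gene only, the list lay at percentile 89.8, inside the range. With regions inside the gene, 7 of 31 lists lay above their length-matched range (a different set from the 8 with all regions): neuronal transcription factors, neuronal cytoskeleton, Wnt signalling, immediate early genes, cell cycle, chromatin regulators and astrocyte markers. Glutamate receptors, ion channels and axon guidance did not, and no biological explanation was tested.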

How the results depend on the processing

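No paired analysis was possible because the lists pool the libraries of each condition and hold no values by replicate. For the same reason no library was left out. Sequence content was not run, as no genome sequence was used. The settings without the tied regions, by score range and over protein-coding genes, and every setting of the common promoter lists, were chosen after seeing the data. Of the alternative values for the main results, 43 stayed on their side, 19 moved, 5 lost their call and 3 reversed. For the gene lists, a value stayed when the number of lists outside the range did, even where the list itself was another. For single genes and the apoptosis list the counts were 32, 27, 6 and 3. Except where the setting itself removes regions or genes, the cause was not tested.

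The BIBR1532 share of regions (46.5%) was 45.4% at a score of at least 2, 44.9% at 3, 47.6% at 500 bp or wider and 48.2% without the tied regions. It reversed to 58.4% at scores under 3. A shared limit takes different pileups in each list, and how far that accounts for the reversal was not tested. The BIBR1532 share was 62.1% below each list's tied score, also a reversal, 44.8% at it and 40.5% above it. These limits differ between the lists (6.34 and 5.19). The share of covered length was 48.4% without the tied regions. The promoter odds ratio lost its call at a score of at least 3 (1.08), at 500 bp (1.02), without the tied regions (1.002) and, within 1 kb of a start site, without them (1.03). At 500 bp 2 region classes passed, and 7 did for common against condition-specific regions. The neighbour ratio was 1.14 at 500 bp and reversed to 0.958 within 200 bp. The shared share of BIBR1532 genes was 25.7% at 500 bp, 26.4% within 10 kb of a start site and 42.3% without the tied regions. Gene lists outside the range numbered 0 at a score of at least 2, within 10 kb, without the top member and with genes as units, and 2 without matching. Common promoter lists outside by percentile (8) numbered 2 at 500 bp and 15 with centres within 1 kb of a start site. The excess reversed for Anks1b at 500 bp (-1), Tox3 without the tied regions (-2) and Lsamp within 10 kb (2).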

Other observations

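The observations on list promoters and on gene density were all made after seeing the data.

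Promoter regions found in a single condition-specific list set no gene list apart after adjustment. In the neuronal transcription factor list, 8 genes had a BIBR1532 promoter region without a vehicle one, among them Neurod1, Lhx2 and the RNA-binding Rbfox3. In that list 1 gene (Neurod6) had the reverse (exact binomial p = 0.0177, adjusted p = 0.512). Among neurotrophin and growth factor genes 9 had a BIBR1532 promoter region without a vehicle one, among them Bdnf, Creb1, Mtor and Fgfr1, and 2 (Ntrk2 and Sort1) the reverse (exact p = 0.0331, adjusted p = 0.512). Neuronal cytoskeleton genes had 2 (Map1a and Mapt) against 9, the latter including Tubb3, Stmn2 and Map4 (exact p = 0.0673, adjusted p = 0.695). Over all protein-coding genes the counts were 1439 and 1545, with 69 genes having both, and 2 of 31 lists had an unadjusted p under 0.05.

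Condition-specific regions inside genes were denser in some gene lists than in length-matched random lists. Immediate early genes had 4.80 regions per 100 kb, against a median of 2.07 in length-matched random lists (percentile 99.9), and neuronal cytoskeleton genes 2.26 against 1.17. Chromatin regulators had 1.91 against 1.20, cell cycle genes 3.15 against 1.71 and astrocyte markers 2.93 against 1.21. Glutamate receptor genes (0.657 against 0.903, percentile 6.44) and telomere and shelterin genes (0.796 against 1.52, percentile 4.78) lay low within their ranges.

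Regions of different lists overlapped in 348 cases, 148 between BIBR1532 and common regions and 200 between vehicle and common regions, with a longest overlap of 774 bp.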
